A study of Capra hircus with 21 samples.

How the data were processed

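RNA was profiled by high-throughput sequencing in goat (Capra hircus) oocytes matured in the animal and in embryos recovered at the 2-cell, 4-cell, 8-cell, 16-cell, morula and blastocyst stages. There were 3 libraries per stage, lettered A to C, and 21 in all. Samples were placed in their stage by their titles, and the labels do not say whether libraries of a stage came from separate animals, how many oocytes or embryos each held, or that a letter joins samples of different stages. The p-values therefore measure only the spread between these samples, which may be technical.

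The authors deposited 1 table of RPKM values (reads scaled by the length of the gene and the size of the library) with a column per library and a row for each of 19040 genes, of which 17446 were protein coding and 1379 were lincRNA genes, per the file headers. The symbol column held a gene name for 13323 genes and an Ensembl identifier for the other 5717. FastQC, STAR 2.5.3a and Partek were used, per the submitters' processing notes, which give no role or order. The genome build, the strandedness of the libraries, the handling of reads that match several genes and the counting rule are not given in the sources used here. Coordinates are printed as the table gives them. Reads from near-identical gene copies, from overlapping genes and from opposite strands may therefore be shared between genes, which makes the values of ribosomal protein, histone, actin and tubulin genes uncertain.

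The unit was checked on the values. The lowest value in every library was 0.01. After subtraction of 0.01 and multiplication by the distance from the start to the stop of the gene, 91.5 to 93.4% of the low values in a library were whole multiples of a single step, within 0.05 of a step. The deposited RPKM values therefore carry an offset of 0.01 and are divided by the whole span of the gene, introns included, so a long gene has a low value for the same number of reads. The step gives the depth: 8.47 M (morula B) to 26.7 M (2-cell C) reads lay in the listed genes, 24.4 to 42.0% of an implied total of 24 to 66.6 M. For a gene spanning 10 kb, 3 reads amounted to 0.00450 to 0.0125 RPKM, which is the level below which a gene cannot be told from a count of 0. This floor covers counting error only, since reads were not marked by molecule.

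Before the data were examined, 7 stage comparisons, 25 gene lists, the rule for the genes named and the alternatives were fixed. The design had covered count tables, normalized values and log values, and the branch for normalized values was used. Genes with at least 1 RPKM in at least 3 libraries (4253 genes) were tested on log2(RPKM + 1) with limma 3.58.1 (trend and robust variance estimation) in R 4.3.3, in a single model of the 7 stages and all 21 libraries. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 over the genes tested and its absolute log2 fold change was at least 1; tests were two-sided. Fold changes are on the log2(value + 1) scale and understate the change of low genes. Change at any stage was a moderated F test over the 6 consecutive comparisons. Numbers of detected genes were compared with exact two-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

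Of the 923 gene symbols on the 25 lists, 676 were found. The share differed between lists. Found were 30 of 78 ribosomal protein, 41 of 77 oxidative phosphorylation and 23 of 38 maternal-effect genes, but 57 of 63 histone modifier genes. Member counts below are out of the members tested, not of the whole list. Lists were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over 114 tests (19 lists with at least 3 members tested, 6 consecutive comparisons), with camera at a correlation estimated from the data (statmod 1.5.0) and limma's fry as alternatives. Camera compares a list with the other genes tested, while fry tests it against no change, so a shift of the median gene can move fry. The 5 marker lists hold genes typical of other cell types that samples flushed from a female tract could carry. Members called are given over all genes tested and adjusted over the list alone. The genes named are, for each consecutive comparison, up to 6 rises and 6 falls with the largest fold change among called genes that carry a symbol, whose libraries do not overlap between the stages and whose mean reaches 10 RPKM in the higher stage (4 of each from oocyte to blastocyst). Added to these are up to 2 rises and 2 falls in each list that was called or had at least 20% of its tested members called, and 35 genes tracked through every stage. The tracked genes ZP3, KDM4E, ZSCAN4, SOX17, KRT18, DPPA3, XIST, NPM1 and NCL were not analysed here. Some of the genes this rule selects are not reported here.

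Alternatives fixed in advance were pseudocounts of 0.1 and 5, a filter of 5 RPKM in 3 libraries, no filter, quantile normalization, median-ratio scaling, array weights, the letter as a replicate block, only the 2 stages compared, no fold threshold, and each library left out in turn. With array weights, blastocyst A weighed 31.0 against 0.214 and 0.164 for blastocyst B and C. That setting therefore leaned on a single blastocyst library, and its counts are the less certain for it. Chosen after the data were seen were a scale from which the gene span was removed (RPM, reads scaled to the reads in all genes of the library, with genes at 1 or more in 3 libraries, 12763 genes), the same scale with the mitochondrial genes left out, and RPKM and RPM without 16-cell C and morula C. The test was tried on counts simulated from the mean 8-cell profile with a dispersion of 0.1. Among 200 genes changed 4-fold, 81, 73 and 75% were called in simulations of the oocyte to 2-cell, 8-cell to 16-cell and morula to blastocyst comparisons, and among 200 changed 2-fold 13.5, 12 and 9.5%, with 1 to 3 false calls and 0 calls of the wrong sign. A 2-fold rise had a median log2(RPKM + 1) change of 0.747 to 0.756, under the threshold of 1, which holds these calls down. The simulation had no outlying libraries and no shift of many genes, so false calls may be more frequent in the real data. Changed genes may also be missed more often. The dispersion was the same for every gene and was not estimated from the libraries. Outlying libraries widen the shared spread: from 4-cell to 8-cell 29 genes were called, and 72 without 16-cell C and morula C. Library pairs of a stage differed by more than counting noise (chi-square per degree of freedom 34.1 to 650), a spread that library preparation alone can bring, so it does not show whether they are separate samples.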

Results

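GDF9, an oocyte-secreted growth factor, was present at 63.2 ± 8.78 RPKM (mean ± SD, n = 3 libraries in this and every other stage) in oocytes and 191 ± 15.2 RPKM at the 8-cell stage, and had dropped to 0.0527 ± 0.0125 RPKM in blastocysts. KRT8, a keratin of epithelia, had no read in any oocyte library and reached 114 ± 39.3 RPKM in blastocysts. KLF17, a zinc-finger transcription factor of early embryos, had no read in oocytes or at the 2-cell stage and was highest at the 16-cell stage (59.2 ± 32.1 RPKM). Of 4253 genes tested, 3991 (93.8%) differed across the 7 stages in the moderated F test. The first principal component (60.8% of the variance) separated libraries up to the 8-cell stage (-45.0 to -36.5) from morula A and B and the blastocysts (66.8 to 78.4), with 16-cell A and B at 35.8 and 40.5. Nearer to the preceding stage than their stage mates lay 16-cell C at 7.60 and morula C at 37.3, against 74.3 and 72.3 for morula A and B. Correlations between libraries of a stage ran from 0.868 to 0.988. Those between 2-cell and 4-cell libraries ran from 0.947 to 0.985. Their mean was 0.964, against 0.967 within each of these stages, so stage mates were hardly closer than these neighbours.

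**Figure D1:**
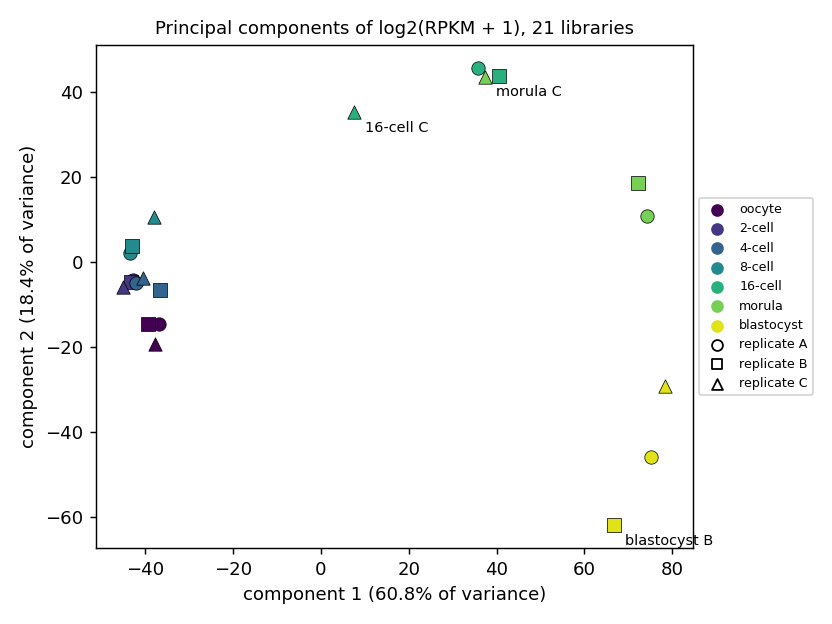
Oocytes and embryos up to the 8-cell stage lie together and the later stages spread away from them. The 21 libraries are drawn on the first 2 principal components of log2(RPKM + 1).

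Genes at 1 RPKM or more numbered 2401 ± 177 in oocytes, 2927 ± 43.4 at the 2-cell, 2799 ± 36.7 at the 4-cell, 2890 ± 31.5 at the 8-cell and 2712 ± 179 at the 16-cell stage, 2820 ± 212 in morulae and 2045 ± 403 in blastocysts (n = 3 each). Every consecutive difference except 16-cell to morula (0.6) gave an exact two-sided permutation p of 0.1, the smallest possible with 3 libraries against 3, and adjusted over the comparisons none was below 0.12. Among the most abundant transcripts of genes with a symbol, PAIP1, a translation regulator, and BTG4, a deadenylation adaptor needed for maternal mRNA clearance, led in oocytes, and the mitochondrial genes COX1 (7.31% of gene reads), COX3 (6.89%) and ND2 (4.38%) in blastocysts. Depth differed by stage, from 24.8 ± 1.73 M gene reads at the 2-cell stage to 13.2 ± 1.84 M in blastocysts.

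**Figure D2:**
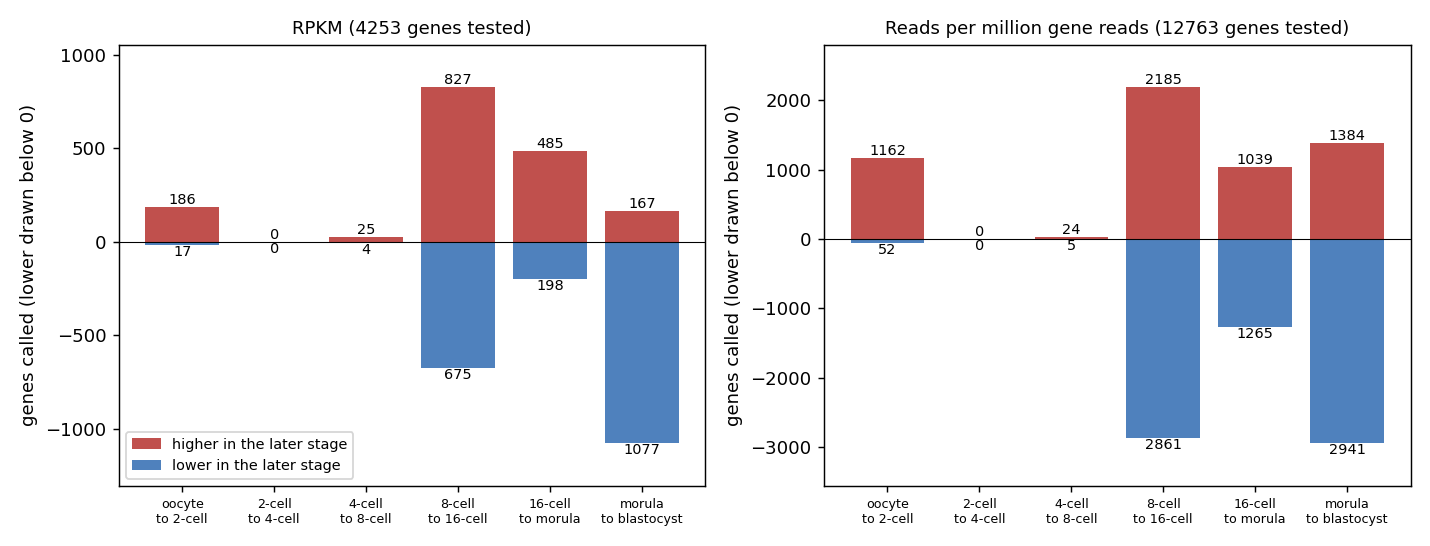
Most calls between consecutive stages fell at 8-cell to 16-cell and morula to blastocyst. Genes called higher and lower are given for RPKM and for the scale without the gene span.

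Between oocyte and 2-cell stage, POLR2G, a subunit of RNA polymerase II, rose from 1.44 ± 0.306 to 14.5 ± 0.743 RPKM (log2 fold change 2.67, SE 0.60, adjusted p = 0.00729). MRPL17, a protein of the mitochondrial ribosome, rose from 2.04 ± 0.47 to 16.1 ± 5.34 (2.46, 0.000688), with the log2 fold change and the adjusted p in brackets here and below, and TENT5C, a poly(A) polymerase, from 1.33 ± 0.734 to 10.7 ± 2.06 (2.37, 0.000445). The replacement histone gene H2AFX went from 4.8 ± 2.25 to 26.3 ± 11 (2.21, 0.0059). Rises of HIST2H2BF from 11.9 ± 3.59 to 70.3 ± 29.5 (2.42, 0.0361) and of NAA11, an N-terminal acetyltransferase, from 1.9 ± 1.01 to 12.9 ± 0.802 (2.31, 0.0237) depended on single libraries. Neither was called with median-ratio scaling. The adjusted p of HIST2H2BF reached 0.146 without oocyte A, B or C or 2-cell A or C, and that of NAA11 0.0927 without oocyte B or C or any 2-cell library. DTWD1, a tRNA-modifying enzyme, fell from 14.2 ± 2.6 to 5.11 ± 1.98 (-1.35, 0.00898), a call lost without 2-cell C (0.0587) and on the scale without the gene span. RPL27 fell from 69.4 ± 13.1 to 23.2 ± 8.85 (-1.59, 0.0374), with adjusted p up to 0.158 without oocyte A, B or C or 2-cell B or C.

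In all, 186 genes were higher and 17 lower at the 2-cell stage (91.6% higher), 66 of them without a symbol. The split depends on scaling. Quantile normalization gave 112 higher and 83 lower (57.4% higher), median-ratio scaling 76 and 85 (47.2%), and RPM without the gene span 1162 and 52. The median gene rose by 0.19 log2 units. The count was 110 without oocyte C, 123 without 2-cell C and 228 higher and 33 lower without 16-cell C and morula C. Ribosomal protein genes were the only list called on RPKM with camera at its preset correlation, lower by 0.20 relative to the median gene (30 tested, 0 higher and 1 lower, adjusted over the list alone 0 and 0, adjusted p = 0.00733, 0.933 with an estimated correlation). Without the gene span, histone modifier and chromatin remodeler genes were also called, 8 of 56 higher and 0 lower (list alone 14 and 0, 0.0115, 0.967 with an estimated correlation). On RPKM at most 2 members were called in each of the other lists, 2 in the spliceosome, oxidative phosphorylation and junction lists, and 0 among maternal-effect factors, whose median (0.34) and test direction (down, 0.963) differed in sign. With fry the ribosomal list was not called (0.844), and the pluripotency (0.000241), stress (0.00766), junction (0.0199) and histone modifier (0.047) lists were called higher. None of the lists called higher was called in camera with an estimated correlation, and fry does not allow for the rise of the median gene.

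From the 2-cell to the 4-cell stage, GDF9 went from 217 ± 50.9 to 147 ± 12.1 RPKM and BTG4 from 279 ± 62.3 to 300 ± 43 RPKM, and neither was called. KLF17 was too low in 4-cell embryos to be told from a count of 0. The list of 13 mitochondrially encoded genes was called higher with 0 members called (median log2 0.41, adjusted p = 0.00733, 0.933 with an estimated correlation, 0.655 with fry, 0.130 with quantile normalization). The ribosomal protein list was called higher by a median of 0.14 (0 members called, 0.0351, 0.933 with an estimated correlation, 0.792 with fry). The nucleolar and ribosome biogenesis list was called lower by a median of -0.17 (0 members called, 0.0445, 0.933 with an estimated correlation, 0.419 with fry), but not with the letter as a replicate block (0.0505) or without the gene span (0.0597). In limma 0 of 4253 genes were called, 161 had an unadjusted p below 0.05, and the lowest adjusted p was 0.329. Other settings gave 1 gene with a pseudocount of 0.1, 3 higher and 2 lower with array weights, 1 lower without 16-cell C and morula C, and 0 without the gene span, where 230 of 12763 genes had an unadjusted p below 0.05. In simulations of 3 other comparisons a 2-fold change was called in 9.5 to 13.5% of the genes changed, and none was run for this one.

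H2AFZ, a replacement histone gene of promoters, rose from 2.18 ± 1.94 to 105 ± 55.8 RPKM (log2 fold change 5.13, SE 0.54, adjusted p = 3.71e-05) between the 4-cell and the 8-cell stage and continued to 814 ± 427 RPKM at the 16-cell stage. HIST2H2AC rose from 5.24 ± 2.31 to 32.1 ± 13.4 (2.39, 0.028), but its adjusted p reached 0.128 without 4-cell A or C or 8-cell B or C, and 0.0847 without the gene span. Both belong to histone families of similar sequence, and shared reads were not excluded. KLF17 stood at 1.57 ± 0.718 RPKM and EIF1AX, a translation initiation factor, at 2.36 ± 0.0604 RPKM in 8-cell embryos. Counts were 25 genes higher and 4 lower, 15 of them without a symbol, and 24 and 5 without the gene span. The count fell to 12 without 8-cell B and 14 without 4-cell B, and rose to 57 higher and 15 lower without 16-cell C and morula C. The share of higher genes, 86.2%, was 59.1% (52 and 36) with quantile normalization and 43.3% (84 and 110) with array weights. The ribosomal protein list was called lower by a median of -0.23 (0 members called, 0.0281, 0.933 with an estimated correlation, 0.419 with fry) and the oxidative phosphorylation list by -0.22 (0 members called, 0.0109, 0.933 with an estimated correlation, 0.532 with fry). The proteasome list was called lower only without the gene span (0.0191, 0.967 with an estimated correlation). In the M phase list 2 genes rose when adjusted over the list alone, and 0 over all genes.

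Between the 8-cell and the 16-cell stage, S100A10, a binding partner of annexin, rose from 0.188 ± 0.188 to 58.7 ± 38 RPKM (log2 fold change 5.46, SE 0.46, adjusted p = 5.38e-08). RPL26, of the large ribosomal subunit, rose from 0.772 ± 0.354 to 62.2 ± 19 (5.13, 1.82e-08), PTRH2, a mitochondrial peptidyl-tRNA hydrolase, from 8.38 ± 2.48 to 326 ± 118 (5.08, 1.94e-07) and the cathepsin CTSV from 0.66 ± 0.289 to 45.3 ± 14.9 (4.76, 5.09e-05). KLF17 rose from 1.57 ± 0.718 to 59.2 ± 32.1 (4.39, 5.89e-07) and KLF4, a pluripotency-associated factor, from 1.49 ± 0.248 to 43.8 ± 18.1 (4.08, 1.81e-07). DNAJB9, a chaperone of the endoplasmic reticulum, rose from 6.47 ± 0.642 to 156 ± 45.6 (4.35, 2.3e-06). EIF1AX, often used as a marker of embryonic genome activation, rose from 2.36 ± 0.0604 to 19.8 ± 10.8 (2.51, 1.03e-05). By the coordinates of the table, S100A10 lies at 3:101786181-101790056 and KLF17 at 3:18835386-18836815.

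Over the same interval GDF9 went from 191 ± 15.2 to 24.8 ± 28.5 RPKM (log2 fold change -3.48, SE 0.65, adjusted p = 0.000202), and ZP4, a zona pellucida glycoprotein, from 43 ± 14.6 to 3.77 ± 3.78 (-3.42, 7.99e-06). MPHOSPH9 fell from 53 ± 15.7 to 7.88 ± 6.38 (-2.78, 9.17e-05), DEPDC7 from 40 ± 4.48 to 7.02 ± 6.09 (-2.60, 0.000527), TRIM77 from 48.8 ± 4.89 to 9.22 ± 8.48 (-2.59, 0.00111) and FBXO43, an inhibitor of the anaphase-promoting complex, from 12.5 ± 2.21 to 1.35 ± 0.983 (-2.58, 1.97e-05). DNMT1, the maintenance DNA methyltransferase, fell from 13.1 ± 4.88 to 3 ± 2.35 (-1.90, 0.00355). BMP15 fell from 84.5 ± 10.5 to 25.9 ± 17.4 (-1.84, 0.0168) and MOS, a kinase of meiotic arrest, from 35.1 ± 4.64 to 9.32 ± 3.85 (-1.86, 0.0166), and these 2 calls were lost without 16-cell A or B (up to 0.0713 and 0.0602). The linker histone gene H1FOO fell from 18.7 ± 2.46 to 7.01 ± 7.15 (-1.65, 0.0249), with up to 0.119 without 8-cell A or B or 16-cell A or B. None of the last 3 was called without the gene span. BTG4 had a mean of 174 RPKM at the 8-cell and 72.2 RPKM at the 16-cell stage and was not called on RPKM. In 16-cell C the maternal genes stood higher than in 16-cell A and B, GDF9 at 57.6 against 7.05 and 9.71 RPKM and BTG4 at 130 against 49.4 and 37.5 RPKM, and KLF17 stood lower, at 22.4 against 73.0 and 82.1 RPKM.

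**Figure D3:**
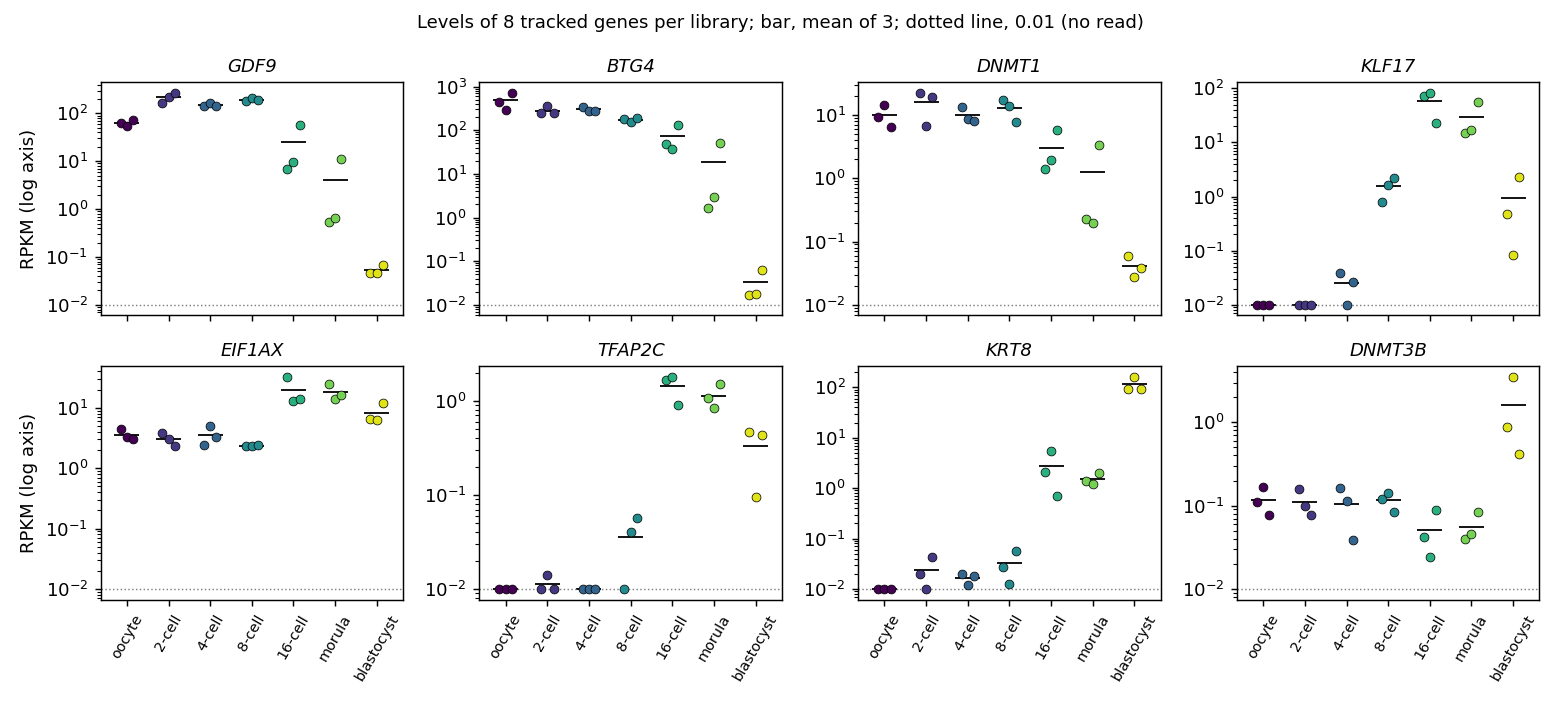
Mean levels of oocyte transcripts (GDF9, BTG4, DNMT1) are lower from the 16-cell stage on and KRT8 is highest in blastocysts. BTG4 was not called from 8-cell to 16-cell, and its mean already stood lower at the 8-cell stage (174 RPKM) than in oocytes (486 RPKM). RPKM of 8 tracked genes is drawn per library on a log axis.

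Genes called numbered 827 higher and 675 lower (518 without a symbol). Without 16-cell C and morula C there were 908 higher and 915 lower, and without the gene span 2185 and 2861, a share of higher genes of 43.3% against 55.1% on RPKM. With quantile normalization it was 49.2%. Of the 1502 genes, 1368 were called with the same sign without the gene span and 0 with the other sign. The median gene fell by 0.14 log2 units. Among 1415 genes that rose in any consecutive comparison, 797 had their first rise here, 285 at 16-cell to morula, 186 at oocyte to 2-cell, 124 at morula to blastocyst and 23 at 4-cell to 8-cell.

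At this step 4 lists were called higher and 1 lower. Ribosomal protein genes rose in 24 of 30 with 0 lower (list alone 24 and 0), by 1.68 relative to the median gene (adjusted p = 1.36e-08, 0.908 with an estimated correlation). Among them, RPS18 went from 1.62 ± 0.475 to 32.3 ± 11.8 (3.62, 1.54e-07). Near-identical copies of these genes make single values uncertain. Nucleolar and ribosome biogenesis genes rose in 17 and fell in 3 of 31 (list alone the same), by 1.22 relative to the median gene (0.00733, 0.933 with an estimated correlation). NHP2, of the small nucleolar RNA particle, went from 0.434 ± 0.0207 to 13.5 ± 6.24 (3.23, 5.43e-06) and IMP3 from 1.51 ± 1.06 to 44.4 ± 22.3 (4.15, 1.98e-05). The export adaptor NMD3 fell from 6.47 ± 0.337 to 1.01 ± 0.876 (-1.98, 7.54e-06) and UTP20 from 5.15 ± 2.06 to 0.901 ± 0.352 (-1.65, 0.000151). Genome-activation factors rose in 8 of 12 with 0 lower (list alone 8 and 0), by 1.88 relative to the median gene (0.0018, 0.424 with an estimated correlation). Of the 22 members found, 6 had a mean of at least 1 RPKM at the 8-cell and 10 at the 16-cell stage. The filter thus favoured rises in this list. Trophectoderm factors rose in 4 of 6 (list alone 4 and 0), by 1.47 relative to the median gene (0.0406, 0.424 with an estimated correlation), but the list was not called with quantile normalization (0.0737) or without the gene span (0.0948). Of the 22 trophectoderm members found, 0 had a mean of at least 1 RPKM at the 8-cell and 4 at the 16-cell stage. Members thus passed the filter mainly through later stages and had little room to fall here. The rise of this list was largely fixed by the filter. Of its members, BMP4 rose from 0.846 ± 0.182 to 6.82 ± 1.84 (2.06, 2.1e-06), KRT8 from 0.0322 ± 0.0227 to 2.8 ± 2.5 (1.66, 0.00026) and TFAP2C from 0.0357 ± 0.0235 to 1.45 ± 0.484 (1.22, 3.51e-06). Maternal-effect factors fell in 11 of 15 with 0 higher (list alone 11, 13 without 16-cell C and morula C), by -1.56 relative to the median gene (0.004, 0.933 with an estimated correlation).

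The other lists were not called on RPKM with camera. With fry the pluripotency, stress and glycolysis lists were called higher (1.72e-05, 0.000241 and 0.00505) and the cholesterol, M phase and DNA methylation lists lower (0.000584, 0.0337 and 0.0373). An estimated correlation in camera gave no call for any of them. In pluripotency and inner cell mass factors 3 rose and 1 fell of 7 (0.561). SOX15 rose from 0.744 ± 0.0405 to 6.27 ± 3.81 (1.92, 0.000188) and PRDM14 from 0.0935 ± 0.0745 to 3.46 ± 1.3 (1.98, 1.95e-07). GDF3 fell from 3.97 ± 0.6 to 1.67 ± 2.07 (-1.16, 0.0339), a fall that was not called without the gene span and reached 0.186 without any 8-cell library or 16-cell A or B. SALL4 rose from 1.91 ± 0.0985 to 5.19 ± 0.525 (1.09, 0.000255). In the M phase list 4 rose and 13 fell of 33 (0.218). The cyclin gene CCNE1 rose from 0.886 ± 0.25 to 12.5 ± 7.56 (2.65, 1.03e-05) and the replication licensing inhibitor GMNN from 11.2 ± 1.49 to 60.7 ± 29.4 (2.24, 0.00187). The kinase TTK fell from 11.3 ± 1.13 to 2.79 ± 1.4 (-1.77, 0.00114), and CENPF, a kinetochore protein, from 40.2 ± 8.65 to 10.2 ± 8.02 (-2.09, 0.00471). Stress and apoptosis genes rose in 6 and fell in 1 of 14 (0.0776, but 0.00628 without the gene span and 0.51 there with an estimated correlation). TXN, a thioredoxin, rose from 0.421 ± 0.449 to 9.03 ± 5.42 (2.73, 1.87e-05) and MCL1 from 1.95 ± 0.271 to 12.7 ± 5.54 (2.13, 0.00025). Spliceosome genes rose in 8 of 26 (0.416), SF3B5 from 12.5 ± 7.72 to 107 ± 2.93 (3.15, 2.13e-05) and LSM8 from 0.526 ± 0.155 to 5.98 ± 1.78 (2.17, 0.000193). Cholesterol and lipid genes fell in 5 of 8 (0.0735). HMGCS1 fell from 42.1 ± 6.9 to 10.7 ± 7.43 (-2.05, 0.00626), though not without the gene span (0.13), and FABP3 from 19.9 ± 3.82 to 8.61 ± 10.3 (-1.66, 0.0133) with up to 0.111 without 16-cell A or B. Cell junction genes fell in 4 of 11 (0.624), the claudin gene CLDN12 from 20.8 ± 0.936 to 5.59 ± 3.14 (-1.84, 0.000863) and the connexin gene GJC1 from 23 ± 2.11 to 7.11 ± 2.46 (-1.60, 0.00338).

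RNA polymerase II and general transcription genes rose in 3 and fell in 4 of 23 (0.932). POLR2I went up from 0.224 ± 0.124 to 18.8 ± 9.02 (3.89, 5.48e-07), the kinase CDK7 down from 10.7 ± 0.565 to 2 ± 1.59 (-2.09, 3.73e-05) and GTF2A2 down from 8.53 ± 2.13 to 2.56 ± 1.67 (-1.49, 0.00232). DNA methylation genes rose in 1 and fell in 3 of 6 (0.534). GADD45A, a stress and demethylation factor, went up from 4.1 ± 1.2 to 13 ± 4.38 (1.43, 0.00163) and UHRF2 down from 3.7 ± 1.56 to 0.58 ± 0.173 (-1.52, 0.000951). Deadenylation and decay genes rose in 4 and fell in 1 of 18 (0.938), with a median of -0.19 and a mean of -0.02 against a test direction of up. YTHDF2, a reader of methylated RNA, went up from 0.11 ± 0.0384 to 1.63 ± 0.473 (1.23, 1.07e-05) and CNOT10 down from 2.25 ± 0.522 to 0.343 ± 0.199 (-1.27, 1.57e-05). Proteasome genes rose in 2 and fell in 3 of 25 (list alone 1 and 3, 0.963). PSMB3 went up from 2.48 ± 0.769 to 10.4 ± 1.99 (1.73, 0.00506), PSMA4 down from 99.9 ± 19.8 to 34.1 ± 24.1 (-1.72, 0.00614) and PSMA5 down from 34.7 ± 2.48 to 9.83 ± 10.8 (-2.18, 0.00392). Oxidative phosphorylation genes rose in 7 and fell in 1 of 36 (list alone 7 and 0, 0.3), COX6B1 from 1.65 ± 0.675 to 10.1 ± 0.643 (2.09, 6.03e-05) and NDUFA2 from 1.3 ± 0.914 to 10.4 ± 3.65 (2.33, 4.28e-05). Mitochondrially encoded genes rose in 2 of 13 (list alone 0, 0.0776), and in 9 of 13 without the gene span (0.00298, 0.901 with an estimated correlation). Glycolysis and glucose uptake genes rose in 1 of 3 (0.555), the glucose transporter gene SLC2A3 from 0.17 ± 0.158 to 2.53 ± 1.12 (1.55, 2.53e-06). In histone modifier and chromatin remodeler genes 1 rose and 1 fell of 10 (0.668), and the riser, the deacetylase HDAC2, went from 0.526 ± 0.0571 to 7.17 ± 1.99 (2.39, 7.4e-07).

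From the 16-cell stage to the morula, LGALS1, a galectin, rose from 2.76 ± 1.21 to 40.5 ± 27 RPKM (log2 fold change 3.23, SE 0.43, adjusted p = 5.54e-05). Subunits of mitochondrial complex I rose as well, NDUFS5 from 0.772 ± 0.557 to 16.4 ± 9.67 (3.19, 1.74e-05) and NDUFB4 from 1.29 ± 0.751 to 15.2 ± 8.8 (2.73, 0.000323). CTSV rose from 45.3 ± 14.9 to 418 ± 213 (3.06, 0.00741) and RPL27 from 22.5 ± 2.08 to 192 ± 108 (2.81, 0.000524). The cold-inducible RNA-binding protein gene RBM3 fell from 170 ± 164 to 11.2 ± 8.54 (-3.42, 0.000931), PCDH8, a protocadherin, from 20.5 ± 7.87 to 2.75 ± 2.56 (-2.75, 8.56e-05), the circadian repressor CIART from 52.8 ± 19.6 to 13.5 ± 15.6 (-2.53, 0.00426) and TUBA4A from 11.4 ± 8.01 to 1.49 ± 1.17 (-2.26, 0.000179). NUFIP2 fell from 15.9 ± 10.7 to 2.45 ± 1.85 (-2.19, 0.000923), and the interferon-induced gene IFIT5 from 43.3 ± 23.5 to 6.68 ± 10.5 (-3.51, 0.0149), with up to 0.102 without 16-cell C or morula A or B.

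BTG4 fell from 72.2 ± 50.1 to 19 ± 28.9 RPKM (log2 fold change -2.94, SE 0.73, adjusted p = 0.00685), a call lost without morula A (0.0611). GDF9 fell from 24.8 ± 28.5 to 4.09 ± 6.05 (-2.46, 0.00977) and BMP15 from 25.9 ± 17.4 to 7.96 ± 11.3 (-2.29, 0.0112), both lost without 16-cell C or morula A or B (up to 0.0737 and 0.102). MOS fell from 9.32 ± 3.85 to 4.36 ± 7.03 (-1.81, 0.041), a call lost when any library of the 2 stages other than morula C was left out (up to 0.249). BTG4, GDF9, BMP15, MOS, IFIT5, RBM3, CIART, TUBA4A and NUFIP2 were not called when only the 2 stages were fitted. In morula C, GDF9 stood at 11.1 against 0.541 and 0.647 RPKM in morula A and B, BTG4 at 52.3 against 1.65 and 3 RPKM and KLF17 at 54.9 against 14.7 and 17.2 RPKM. Its percentage of gene reads in mitochondrial genes was 3.23.

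There were 485 genes higher and 198 lower (346 without a symbol). Without 16-cell C and morula C there were 581 and 410. The count was 385 without morula A and 1074 without morula C. The share of higher genes, 71.0%, was 58.5% with quantile normalization (352 and 250), 52.9% with median-ratio scaling (342 and 305) and 45.1% without the gene span (1039 and 1265). Of the 683 genes, 621 were called with the same sign without the gene span.

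Ribosomal protein genes rose in 27 of 30 with 0 lower (list alone 28 and 0), by a median of 1.93 (adjusted p = 4.47e-15, 0.424 with an estimated correlation), and in 18 with quantile normalization. Oxidative phosphorylation genes rose in 20 of 36 with 0 lower (list alone 23 and 0, 27 without 16-cell C and morula C, median 1.15, 1.12e-11, 0.865 with an estimated correlation). Proteasome genes rose in 5 of 25 (list alone 5, median 0.68, 0.0351, 0.933 with an estimated correlation, 0.118 with fry). PSMC5 rose from 1.35 ± 1.39 to 8.88 ± 2.93 (2.18, 0.000382) and PSMB3 from 10.4 ± 1.99 to 33.5 ± 4.38 (1.60, 0.0205), the latter with up to 0.0689 without 16-cell C or morula A or B. Maternal-effect factors fell in 5 of 15 (list alone 6, 8 without 16-cell C and morula C, median -1.32, 0.00242, 0.933 with an estimated correlation, 0.122 with fry), and H1FOO was not called (0.118). The deadenylation and decay list was called lower by a median of -0.26 with 1 of 18 members called (0.0381, 0.933 with an estimated correlation), not called with quantile normalization (0.0737), a pseudocount of 0.1 (0.0681) or without the gene span (0.112). In the cholesterol list MSMO1, of sterol synthesis, rose from 14 ± 3.56 to 41.7 ± 10.4 (1.5, 0.00242), though not when only the 2 stages were fitted. HMGCS1 fell from 10.7 ± 7.43 to 2.96 ± 4.76 (-2.11, 0.0132), with up to 0.0929 without 16-cell C or morula A or B, and not when only the 2 stages were fitted. Nucleolar genes rose in 2 of 31 (0.421 on RPKM). Without the gene span they rose in 6 of 43 and the list was called (0.0146, 0.901 with an estimated correlation). Genome-activation, pluripotency and mitochondrially encoded genes had 0 members called.

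Between morula and blastocyst, KRT8 rose from 1.52 ± 0.403 to 114 ± 39.3 RPKM (log2 fold change 5.48, SE 0.32, adjusted p = 1.06e-10). The cytoskeletal actin gene ACTB rose from 6.43 ± 1.2 to 388 ± 207 (5.58, 1.25e-09) and its close paralog ACTG1 from 35.1 ± 20.4 to 392 ± 102 (3.59, 5.13e-07). Genes of the mitochondrial genome rose, COX2 from 599 ± 367 to 9989 ± 3457 (4.28, 1.24e-05) and ND6 from 42.5 ± 34.7 to 377 ± 140 (3.41, 0.000449). SLC35G1, a transmembrane transporter, rose from 1.76 ± 2.14 to 19.6 ± 4.19 (3.18, 7.82e-07) and DAB2, an endocytic adaptor of extraembryonic epithelia, from 0.547 ± 0.61 to 8.75 ± 1.36 (2.72, 8.11e-10). KLF5, a transcription factor of the trophectoderm and inner cell mass, rose from 4.88 ± 3.83 to 18.9 ± 5.64 (2.01, 0.00024), and GDF3 from 0.215 ± 0.186 to 4.95 ± 4.11 (2.05, 0.00115).

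Larger numbers of genes fell. MLLT11 went from 67.8 ± 76 to 0.682 ± 0.412 RPKM (log2 fold change -4.69, SE 0.63, adjusted p = 1.12e-05), the ubiquitin-conjugating enzyme UBE2C of mitotic exit from 188 ± 87 to 10.6 ± 11.5 (-4.55, 1.18e-05), and DDIT3, a stress-induced transcription factor, from 377 ± 391 to 12.1 ± 5.81 (-4.42, 8.06e-06). RHEBL1 fell from 38.2 ± 24.3 to 0.906 ± 0.657 (-4.24, 2.48e-07), TMEM37 from 24.6 ± 24 to 0.0757 ± 0.0692 (-4.14, 1.69e-06) and SFR1, a recombination factor, from 105 ± 25.2 to 7.25 ± 7.36 (-4.07, 4.8e-06). KLF17 fell from 28.9 ± 22.5 to 0.937 ± 1.16 (-3.86, 4.38e-06), MSMO1 from 41.7 ± 10.4 to 2.56 ± 1.19 (-3.62, 7.19e-08), the spindle checkpoint gene MAD2L1 from 41 ± 6.67 to 4.05 ± 4.89 (-3.55, 1.18e-05) and PCNA, the replication clamp, from 249 ± 153 to 39.5 ± 50.5 (-3.35, 0.000733). BTG4 fell from 19 ± 28.9 to 0.0327 ± 0.0263 (-3.00, 0.00272) and BMP15 from 7.96 ± 11.3 to 0.0574 ± 0.0438 (-2.20, 0.00744), while GDF9 (0.0575), MOS (0.0655), H1FOO (0.0891) and DNMT1 (0.185) were not called on RPKM and were called lower without the gene span.

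Counts were 167 higher and 1077 lower (465 without a symbol), and 150 and 1007 without 16-cell C and morula C. The excess of falls depends on scaling. Of the implied reads, 24.4 and 24.9% lay in genes in blastocyst A and B, against 40.5% in blastocyst C and 35.2 to 35.6% in morulae. What this adds to the falls was not tested. The share of higher genes, 13.4%, was 52.0% with quantile normalization (436 and 403), 67.6% with median-ratio scaling (725 and 347) and 32% without the gene span (1384 and 2941). On the latter scale it was 50.5% (2159 and 2115) with the mitochondrial genes left out. The median gene fell by 0.48 log2 units. List shifts worded below as relative to the median gene allow for this fall, and list medians and means given without these words do not. Of the 1244 genes, 1157 were called with the same sign without the gene span.

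Mitochondrially encoded genes rose in 5 of 13 with 0 lower (list alone 5 and 0), by 2.20 relative to the median gene (adjusted p = 1.09e-08, 0.816 with an estimated correlation). All genes on the mitochondrial chromosome, including those outside this list, took up 1.74 ± 1.5% of gene reads in oocytes. Their share was 1.94 ± 0.514, 2.64 ± 1.12 and 3.37 ± 1.31% at the 2-cell, 4-cell and 8-cell stages and 10.2 ± 3.17% at the 16-cell stage. It was 8.92 ± 5.31% in morulae and 36.8 ± 7.96% in blastocysts. Nuclear-encoded oxidative phosphorylation genes rose in 7 and fell in 1 of 36 (list alone the same), by 0.84 relative to the median gene (1.42e-09, 0.908 with an estimated correlation, 0.143 with fry). They rose in 23 with quantile normalization and 29 with median-ratio scaling. NDUFB10 went from 3.58 ± 1.38 to 26.1 ± 9.48 (2.55, 2.09e-05) and UQCRQ from 14.9 ± 6.99 to 69.3 ± 36.3 (2.08, 0.00102). NDUFB2 fell from 9.96 ± 1.49 to 4.4 ± 2.18 (-1.11, 0.00227), with a fold change below the threshold without blastocyst B, no call without the gene span and a log2 change of 0.12 with median-ratio scaling. Stress and apoptosis genes rose in 4 and fell in 3 of 14 (list alone the same), by 1.02 relative to the median gene (0.00522, 0.424 with an estimated correlation), but the list was not called with fry (0.140) or without the gene span (0.0948). GPX1, a peroxidase, rose from 8.19 ± 3.58 to 40.8 ± 14.8 (2.19, 0.000418) and the chaperone HSPA5 from 21 ± 11.7 to 54.9 ± 7.07 (1.53, 0.00388), the latter with a fold change below the threshold without morula A. Trophectoderm factors rose in 2 and fell in 1 of 6 (list alone the same), by 0.82 relative to the median gene (0.0359, 0.424 with an estimated correlation, 0.141 with quantile normalization). BMP4 fell from 6.16 ± 3.04 to 0.238 ± 0.104 (-2.44, 3.88e-07). Without the gene span 10 of 18 rose and 2 fell (list alone 11 and 2, 4.85e-05, 0.0815 with an estimated correlation). Nucleolar genes fell in 18 of 31 with 0 higher (list alone 18), by -0.63 relative to the median gene (0.00242, 0.933 with an estimated correlation), in 5 with quantile normalization, and in 4 with 1 higher with median-ratio scaling. POLR1D, of RNA polymerases I and III, went from 98.3 ± 35.4 to 14.5 ± 7.65 (-2.78, 5.84e-05) and IMP3 from 111 ± 18.7 to 18.9 ± 21.9 (-3.23, 0.000357).

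**Figure D4:**
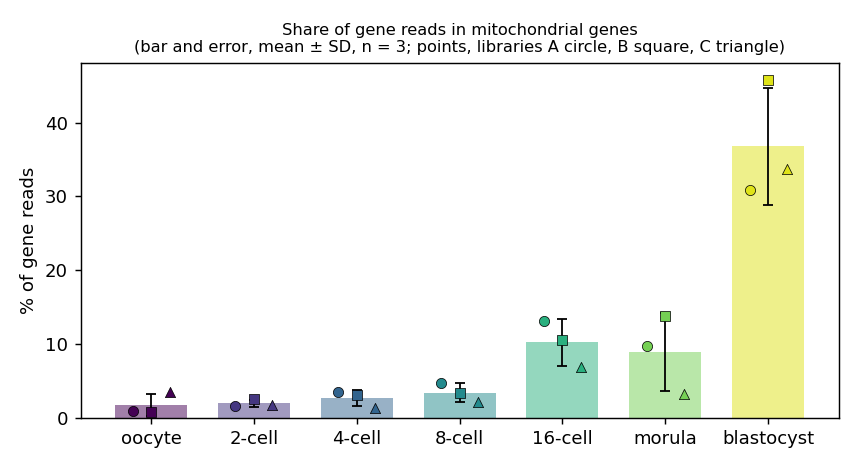
Genes on the mitochondrial chromosome take up a larger share of gene reads in blastocysts than at the other stages. Bars are means ± SD of 3 libraries and points are libraries.

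The remaining lists were not called on RPKM with camera. With fry the M phase, spliceosome, genome-activation, histone modifier, RNA polymerase II, decay and DNA methylation lists were called lower (0.000166 to 0.00964). In camera with an estimated correlation none of them was called, and fry does not allow for the fall of the median gene. M phase genes fell in 14 of 33 with 0 higher (0.0565, but 0.0408 with quantile normalization), and without the gene span in 25 of 52 (0.00328, 0.843 with an estimated correlation). Spliceosome genes fell in 11 of 26 (0.383, but 0.0299 without the gene span and 0.843 there with an estimated correlation), and 1 rose and 1 fell with quantile normalization. SF3B6 went from 39 ± 10.8 to 8.92 ± 6.52 (-2.19, 0.000517) and SNRPB2 from 35.1 ± 3.65 to 8.29 ± 5.87 (-2.13, 0.000312). RNA polymerase II genes fell in 7 of 23 (0.202, 1 with quantile normalization), and the list was called without the gene span (0.0323, 0.967 with an estimated correlation). POLR2G fell from 98.8 ± 72.9 to 18.1 ± 18.7 (-2.53, 0.00213) and POLR2H from 13.3 ± 3.33 to 3.92 ± 3.09 (-1.69, 0.0026). Genome-activation factors rose in 1 and fell in 6 of 12 (0.453, 2 and 1 with quantile normalization). Decay genes rose in 1 and fell in 4 of 18 (0.915), and TUT7, a terminal uridylyltransferase, fell from 2.62 ± 0.59 to 0.268 ± 0.139 (-1.5, 0.000126). Maternal-effect factors fell in 3 of 15 (list alone 2, 0.694), and without the gene span in 13 of 22 (0.000169, 0.901 with an estimated correlation). Histone modifier genes fell in 3 of 10 (0.58), HDAC2 from 8.02 ± 3.74 to 1.2 ± 0.222 (-1.93, 1.32e-05) and EED, of the Polycomb complex, from 3.04 ± 1.08 to 0.757 ± 0.819 (-1.26, 0.000396). SNRPB2, POLR2H, TUT7 and EED were not called with quantile normalization or median-ratio scaling, and SF3B6, POLR2G and HDAC2 not with the latter.

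Proteasome genes fell in 5 of 25 (0.932, rose in 6 with median-ratio scaling), with a median of -0.58 against a test direction of up. PSMA6 fell from 27.5 ± 5.54 to 9.71 ± 11.4 (-1.96, 0.00389). Ribosomal protein genes fell in 3 of 30 (list alone 0, 0.416, rose in 15 with median-ratio scaling), also with a negative median (-0.34) and a test direction of up. Pluripotency factors rose in 1 and fell in 1 of 7 (median -0.05, mean 0.08, 0.365). SOX15 fell from 4.68 ± 1.63 to 1.49 ± 0.731 (-1.19, 0.011) with 0.0721 without blastocyst B, and like PSMA6 was not called with quantile normalization or median-ratio scaling. Cell junction genes rose in 1 and fell in 2 of 11 (median -0.19, test up, 0.21), and without the gene span rose in 10 and fell in 3 of 32 (0.00856, 0.843 with an estimated correlation). Cholesterol and lipid genes rose in 2 and fell in 1 of 8 (median -0.12, test up, 0.478). FABP3 rose from 5.52 ± 2.32 to 27.4 ± 10.3 (2.11, 0.00373) and FDPS from 0.204 ± 0.0548 to 2.57 ± 2.72 (1.26, 0.0182), the latter 0.154 without blastocyst B. DNA methylation genes fell in 1 of 6 (0.827). Glycolysis genes fell in 1 of 3 (median 0.52, mean -0.28, 0.326), with LDH-A from 6.46 ± 4.85 to 0.745 ± 0.852 (-1.91, 0.00334). EIF1AX fell from 18.4 ± 5.78 to 8.28 ± 3.26 (-1.08, 0.0172), but was not called without the gene span, reached 0.0764 without morula A or blastocyst A or B, and changed by 0.27 with median-ratio scaling. Fitted on the 2 stages alone, BMP15, BTG4, KLF5, HSPA5, UQCRQ, NDUFB2, POLR2G, POLR2H, PSMA6, SOX15, FDPS, EED, LDH-A and EIF1AX were not called.

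Long genes rarely reached 1 RPKM. The genes below were tested on RPM, the scale without the gene span, a setting chosen after the data were seen. Some of them are short, such as SOX2. DNMT3B, a de novo DNA methyltransferase, rose there from 4.55 ± 2.29 to 216 ± 240 RPM (4.63, 2.17e-05) between morula and blastocyst, with 3.49 RPKM in blastocyst B against 0.881 and 0.417 in A and C. DNMT3A rose from 16.2 ± 13.2 to 83.7 ± 12 RPM (2.63, 0.000477). GATA3, a trophectoderm transcription factor, rose from 8.5 ± 12.7 to 129 ± 87.2 RPM (4.47, 0.00011), and POU5F1, a pluripotency factor, from 11.4 ± 8.54 to 28.2 ± 12.2 RPM (1.37, 0.0372). TFAP2C fell from 25.8 ± 7.85 to 8.83 ± 6.23 RPM (-1.65, 0.00521) and SOX2 from 4.97 ± 3.77 to 1.67 ± 0.691 RPM (-1.0, 0.0336). POU5F1 and TFAP2C were also tested on RPKM, where neither was called between morula and blastocyst. Earlier, TEAD4, a transcription factor upstream of the trophectoderm, rose from 0.657 ± 0.995 to 6.26 ± 3.4 RPM (2.15, 0.000579) between the 16-cell stage and the morula. NANOG rose from 2.12 ± 0.652 to 11.9 ± 1.08 RPM (2.07, 0.00618) between the 8-cell and the 16-cell stage, and CDH1 fell from 20.2 ± 5.56 to 6.28 ± 4.7 RPM (-1.69, 0.0241) over the same interval, as did DNMT3A from 17.7 ± 3.44 to 6.29 ± 4.42 RPM (-1.53, 0.0248). Primitive endoderm factors, with fewer than 3 members tested on RPKM, rose in 4 and fell in 1 of 17 between morula and blastocyst (0.00884, 0.843 with an estimated correlation). GATA6, ELF5, TET3 and ATP1B1 were not called between these stages.

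Markers of other cell types were tested on the same scale, and none of their 5 lists was called in any comparison. Cumulus and granulosa genes fell in 3 of 7 between the 16-cell stage and the morula (0.399), with STAR as the highest member (mean 4.42 RPKM in oocytes), and summed to 319 RPM in oocytes, 451 at the 2-cell, 352 at the 4-cell, 505 at the 8-cell and 217 at the 16-cell stage, 108 in morulae and 35.7 in blastocysts. Fibroblast and endothelium genes fell in 3 of 8 (list alone 6, 0.075) and summed to 380 in oocytes, 248 at the 8-cell stage and 28.2 in blastocysts. Oviduct and uterine epithelium genes fell in 2 of 4 (0.186) and summed to 12.7 in oocytes, at most to 20 at the 4-cell stage, and to 1.88 in blastocysts. Blood and immune genes fell in 1 of 4 (0.525), with a highest sum of 18.1 at the 16-cell stage, and sperm genes, mainly LDHC, fell in 1 of 3 (list alone 3, 0.1), with a highest sum of 428 at the 4-cell stage. In blastocyst B 11.1% of genes had no read, against 32.3 and 32.7% in blastocyst A and C, and 45.8% of its gene reads were mitochondrial, against 30.8 and 33.7%.

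From oocyte to blastocyst, COX2 of the mitochondrial genome rose from 64.8 ± 37.2 to 9989 ± 3457 RPKM (log2 fold change 7.35, SE 0.58, adjusted p = 2.67e-09), LGALS1 from 0.209 ± 0.0704 to 194 ± 83.5 (7.24, 6.41e-11) and ACTB from 1.98 ± 0.757 to 388 ± 207 (6.92, 2.55e-11). KRT8 went from no read to 114 ± 39.3 RPKM. BTG4 fell from 486 ± 212 to 0.0327 ± 0.0263 (-8.79, 6.4e-09) and PAIP1 from 282 ± 8.88 to 0.823 ± 0.629 (-7.33, 1.23e-06). TMEM60 fell from 1543 ± 266 to 17.8 ± 16.6 (-6.70, 2.84e-07) and TRIM59, a ubiquitin ligase, from 103 ± 12.3 to 0.573 ± 0.304 (-6.06, 3.43e-06). BMP15 stood at 43.4 RPKM in oocytes, 25.9 at the 16-cell stage and 0.0574 in blastocysts. At the same stages DNMT1 stood at 10.1, 3 and 0.0419, EIF1AX at 3.58, 19.8 and 8.28, and SALL4 at 1.68, 5.19 and 5.43. Genes called numbered 842 higher and 1211 lower (781 without a symbol), and 845 and 1217 without 16-cell C and morula C. The share of higher genes, 41.0%, was 49.8% with quantile normalization and 56.8% with median-ratio scaling (1278 and 973), and the median gene fell by 0.33 log2 units. Without the gene span 3180 genes were higher and 4207 lower, or 4132 and 3465 with the mitochondrial genes also left out, and 2023 of the 2051 RPKM calls also tested there were called with the same sign.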

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

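Settings without the gene span, without 16-cell C and morula C together, and without the mitochondrial genes were chosen after the results were seen. The planned DESeq2 alternative was not run because the deposited values are not counts. It was not tried on the read numbers recovered from the step either. Where a value moved, the cause was not tested.

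From oocyte to 2-cell, 203 genes changed. The count was 350 with a pseudocount of 0.1, 48 with a pseudocount of 5, 114 with a filter at 5 RPKM, 318 with array weights, 493 without a fold threshold, 110 to 178 with single libraries left out, 1214 without the gene span, 2088 on that scale without 16-cell C and morula C, and 1118 there without mitochondrial genes. From 2-cell to 4-cell 0 genes changed, 1 with a pseudocount of 0.1, 5 with array weights and 1 without 16-cell C and morula C. From 4-cell to 8-cell 29 changed, 17 with a filter at 5 RPKM, 88 with quantile normalization, 194 with array weights, 12 to 30 with single libraries left out, 72 without 16-cell C and morula C, and 116 without these and the gene span.

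From 8-cell to 16-cell 1502 genes changed, 2329 with a pseudocount of 0.1, 613 with 5, 2432 without a fold threshold, 5046 without the gene span, 6585 there without 16-cell C and morula C, and 4778 there without mitochondrial genes. From 16-cell to morula 683 changed, 1096 with a pseudocount of 0.1, 319 with 5, 185 with only the 2 stages fitted, 1058 without a fold threshold, 385 to 1074 with single libraries left out, and 2304, 3765 and 2378 in the same 3 settings without the gene span. From morula to blastocyst 1244 changed, 2136 with a pseudocount of 0.1, 513 with 5, 689 with only the 2 stages fitted, and 4325, 4046 and 4274 without the gene span. From oocyte to blastocyst 2053 changed, 3082 with a pseudocount of 0.1, 916 with 5, 1348 with a filter at 5 RPKM, and 7387, 7596 and 7597 without the gene span. Change at any stage was called in 3991 genes, in 11166 of 19040 without a filter and in 11025 without the gene span. First rises without the gene span numbered 1162 at oocyte to 2-cell, 2077 at 8-cell to 16-cell, 661 at 16-cell to morula and 1045 at morula to blastocyst.

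With the letter as a replicate block the counts were 198, 0, 24, 1501, 682 and 1241 for the consecutive comparisons, 2049 from oocyte to blastocyst and 3983 at any stage. Between libraries of the same letter in different stages the correlation of residuals had a median of -0.0196 (-0.410 to 0.318) and exceeded 0.1 in 18 of 63 pairs, among them 16-cell C and morula C (0.311). In this replicate block setting the nucleolar list at 2-cell to 4-cell had 0.0505 and the M phase list at morula to blastocyst 0.0462.

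Genes detected from oocyte to blastocyst numbered 6061, 7479, 7160, 7328, 6830, 6617 and 5789 at 0.1 RPKM, and 978, 1135, 1076, 1083, 1178, 1256 and 820 at 5 RPKM.

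No list was called with an estimated correlation, where the adjusted p of the called lists was 0.424, 0.816, 0.865, 0.908 or 0.933. With fry, calls were lost for ribosomal proteins at oocyte to 2-cell (0.844), 2-cell to 4-cell (0.792) and 4-cell to 8-cell (0.419), nucleolar genes (0.419) and mitochondrial genes (0.655) at 2-cell to 4-cell, oxidative phosphorylation at 4-cell to 8-cell (0.532) and morula to blastocyst (0.143), maternal-effect factors (0.122) and proteasome (0.118) at 16-cell to morula, and stress genes at morula to blastocyst (0.140). Fry added, at oocyte to 2-cell, pluripotency (0.000241), stress (0.00766), junctions (0.0199) and histone modifiers (0.047), at 8-cell to 16-cell, glycolysis (0.00505), pluripotency (1.72e-05), DNA methylation (0.0373), M phase (0.0337), stress (0.000241) and cholesterol (0.000584), and at morula to blastocyst decay (0.000588), genome activation (0.000241), RNA polymerase II (0.000359), spliceosome (0.000166), DNA methylation (0.00964), histone modifiers (0.000241) and M phase (0.000166).

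Without the gene span, lists called at the preset correlation had 0.0815 (trophectoderm at morula to blastocyst), 0.338 (ribosomal proteins at 16-cell to morula), 0.410, 0.51 (stress at 8-cell to 16-cell), 0.843, 0.901 or 0.967 with an estimated one, and decay at 16-cell to morula, called only on RPKM, had 0.968. On that scale calls were lost for nucleolar genes at 2-cell to 4-cell (0.0597), trophectoderm at 8-cell to 16-cell (0.0948), decay at 16-cell to morula (0.112) and stress at morula to blastocyst (0.0948), and gained for histone modifiers at oocyte to 2-cell (0.0115), proteasome at 4-cell to 8-cell (0.0191), mitochondrial genes (0.00298) and stress (0.00628) at 8-cell to 16-cell, nucleolar genes at 16-cell to morula (0.0146) and, at morula to blastocyst, maternal-effect factors (0.000169), RNA polymerase II (0.0323), spliceosome (0.0299), junctions (0.00856) and M phase (0.00328). Quantile normalization gave 0.130 for mitochondrial genes at 2-cell to 4-cell, 0.0737 for trophectoderm at 8-cell to 16-cell and for decay at 16-cell to morula, 0.141 for trophectoderm and 0.0408 for M phase at morula to blastocyst. A pseudocount of 0.1 gave 0.0681 for decay at 16-cell to morula and 0.0375 for M phase at morula to blastocyst. Among named genes 3 reversed sign, all at morula to blastocyst with median-ratio scaling: EIF1AX (0.27), NDUFB2 (0.12) and SALL4 (1.23).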

Other observations

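The histone genes, the combinations of rises and falls, the test of exchanged labels and the test of marker lists in blastocyst B were chosen after the results were seen. Of 23 genes with a histone symbol tested, 6 rose and 0 fell from oocyte to 2-cell, 0 changed from 2-cell to 4-cell, 2 rose and 0 fell from 4-cell to 8-cell, 3 rose and 2 fell from 8-cell to 16-cell, 0 rose and 9 fell from 16-cell to morula, and 1 rose and 6 fell from morula to blastocyst. They are no fixed list and were not tested as a group. The linker histone gene HIST1H1D rose from 7.33 ± 1.05 RPKM in oocytes to 28.0 ± 4.97 RPKM at the 2-cell stage (n = 3 each, log2 fold change 1.79, limma adjusted p = 0.0127), and the testis and oocyte variant HIST1H2BA from 17.7 ± 5.01 to 76.4 ± 35.7 RPKM (2.00, 0.0136). HIST1H2BA fell from 33.5 ± 21.4 at the 16-cell stage to 6.91 ± 4.92 RPKM in morulae (-2.18, 0.00392) and 0.523 ± 0.237 RPKM in blastocysts (-2.17, 0.00171). The replacement gene H2AFV rose later, from 1.39 ± 0.886 at the 8-cell to 21.6 ± 8.50 RPKM at the 16-cell stage (3.23, 4.45e-07), and fell to 7.28 ± 3.41 RPKM in blastocysts (-1.50, 0.00136). H1F0 fell from 12.8 ± 14.8 to 0.183 ± 0.153 RPKM between morula and blastocyst (-2.94, 0.000417), while H2AFJ rose from 5.80 ± 6.08 to 13.4 ± 8.13 RPKM (1.28, 0.0387). Similar copies of these genes may share reads, and H2AFZ itself went from 814 ± 427 RPKM at the 16-cell stage to 97.6 ± 54.9 RPKM in blastocysts.

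Of 827 genes that rose from 8-cell to 16-cell, 401 fell from morula to blastocyst, where 1077 genes fell, and without the gene span 842 of 2185. KLF17, BMP4, IMP3, HDAC2 and H2AFV are among them. The 2 comparisons share no library. A gene that has risen has more room to fall than a low gene, so no chance value is set beside these counts, and the number that fell depends on scaling.

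The libraries 16-cell C and morula C lay nearer to the preceding stage than their stage mates. An exchange of these 2 labels is argued against by the correlations of 16-cell C, 0.918 with 16-cell A and B and 0.780 with morula A and B (difference 0.138). In a plain mixture of stages, falling and rising genes would imply the same share of the earlier stage. For 16-cell C, falling genes imply an 8-cell share of 0.373 (0.363 to 0.385) and rising genes 0.548 (0.532 to 0.567), a difference of -0.175. For morula C, falling genes imply a 16-cell share of 1.01 (0.931 to 1.13) and rising genes 0.717 (0.691 to 0.745), a difference of 0.294. The ranges in brackets come from resampling genes and leave out the spread of the few reference libraries. The implied shares differ, but a mixture is not excluded. Morula C had a mean correlation of 0.924 with 16-cell A and B and 0.881 with morula A and B. Its correlation with 16-cell C was 0.918, and 16-cell C had a mean of 0.828 with the 8-cell libraries. Embryos at an earlier point of the same stage, or a single wrong label for morula C, may account for these values, and neither was tested.

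In blastocyst B 11.1% of genes had no read, against 32.3% in A and 32.7% in C. More reads do not account for this, since after thinning to equal reads the share was 12.6% in B, 19.7 points under the nearer library (a difference of -19.7). Background reads in proportion to the gene span are argued against, since among the 4525 genes without a read in A and C the reads in B did not follow the span (Spearman rho 0.00628). The other value expected of background was met: mean reads of B in these genes were 5.39, 6.85, 7.26 and 6.48 by quartile of span, against 0.645, 0.566, 0.645 and 0.607 in A among genes without a read in B and C. B was singled out for its few genes without a read, so this excess was largely fixed by that choice. It does not speak for or against background. Background that does not follow the span was not excluded. B had reads in 3212 of the 4525 genes (71.0%), with a median of 6, but they made up 0.205% of its gene reads. Whether B holds RNA of another cell type cannot be told from so few reads: against the higher of A and C, the oviduct and uterine epithelium list stood at 7.56 times (4.79 against 0.634 and 0.210 RPM, mainly FOXJ1 at 2.82), sperm at 3.29, cumulus and granulosa at 2.11, blood at 1.67 and fibroblasts at 0.406. B also had reads in 251 of 256 genes without a read in the 18 libraries of other stages, against 45 in A and 106 in C. No gene of the table was without a read in every library, so these genes had to have one in a blastocyst. The count in B therefore follows largely from its few genes without a read and is no separate trait. A biological difference between these blastocysts was not tested.

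All genes on the mitochondrial chromosome together took up 36.8% of gene reads in blastocysts. Mitochondrial DNA in the libraries is argued against by ND6, the gene listed on the other strand, which reached at most 0.0291 of COX1 in a blastocyst library (0.00974 to 0.0383 in other stages), where DNA would bring both alike. A larger number of mitochondrial transcripts per embryo and a loss of other transcripts cannot be separated by shares of reads, and no biological explanation was tested. With these genes left out, 2159 genes were higher and 2115 lower from morula to blastocyst without the gene span (50.5% higher), against 1384 and 2941 (32%) with them, so the excess of falls on that scale depends on these genes.

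A hypothesis was that genes newly rising at the 8-cell to 16-cell step have short spans. On the scale without the gene span the 2185 rising genes had a median span of 9.41 kb, against 23.2 kb (21.4 to 25.1) in 10000 random lists of like abundance, and the 2861 falling genes 45.5 kb against 24.3 kb (22.9 to 25.9). From morula to blastocyst the 1384 rising genes had 21.7 kb against 21.8 kb (19.7 to 24.1), so the hypothesis was not borne out there. Short spans may mark early transcribed genes in short cell cycles, or may follow from reads in introns of maternal transcripts, and the 2 were not separated.

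Other splits of the libraries were fitted in the same way. With 6 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10, the labelled one, gave as many genes in oocyte to 2-cell (203, highest other 0), 4-cell to 8-cell (29, highest other 0), 8-cell to 16-cell (1502, highest other 1), morula to blastocyst (1244, highest other 170) and oocyte to blastocyst (2053, highest other 0). From 16-cell to morula it was also 1 of 10, with 683 genes against 415 in the split of 16-cell A, 16-cell C and morula C against the rest, which points to a structure of the samples beyond their labels. From 2-cell to 4-cell all 10 gave 0 genes or more, with 2 as the highest other. Over all stages 1 of 100 groupings, the labelled one, gave as many genes (3991, highest other 686), which is the smallest share possible. A random grouping of these libraries is therefore an unlikely source of this count. Whether libraries of a stage are separate samples is not known, so chance differences between animals or pools are not excluded.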
